A study of Homo sapiens with 4 samples.

How the data were processed

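Regulatory T cells from healthy people were cultured for 72 hours with stimulation through CD3 and CD28, with or without 40 mM NaCl added, and total RNA was hybridised to 4 arrays, 2 for each medium. Per the labels' protocols, cDNA was amplified with the Ovation Pico WTA System V2 and biotin-labelled with the Encore Biotin Module. The array platform is not named in the sources used here. The probe set identifiers have the Affymetrix form, with 54675 probe sets, of which 62 are controls.

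The authors deposited a table of log2 expression values, 1 column per array, and a table of their own comparison. The submitters' processing notes name limma, with no version. The background correction, summarisation and normalization of the log2 values are not given in the sources used here. Scale and direction were settled from the values: the range from 2.60 to 15.03 and the near-equal quartiles of the 4 arrays show values on a log2 scale that had been scaled to each other, and the log2 fold change in the deposited comparison equals high salt minus normal salt in the value table within 4.5e-08. Per the file headers, the deposited comparison also holds p-values with adjusted values, and 2 scores, a moderated statistic and a log odds, per probe set. All arrays of the value table matched a sample by name, with 0 columns left over.

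Gene symbols were those in the deposited comparison. Of the probe sets, 36934 had a symbol that is current in the RefSeq gene table of GRCh38.p14, 2649 were updated through that table's synonyms and 1451 kept the symbol of the file. Another 13379 had no symbol and 67 had one that a spreadsheet had turned into a date. These 13446 were tested apart, with 0 past an adjusted p of 0.05 and 176 at an unadjusted p under 0.05. No coordinates are given because the files name no genome build. Another 133 probe sets of genes that carry donor traits (Y-linked genes, XIST, HLA genes and receptor variable segments) were left out of every step. Each gene was represented by its probe set with the highest mean over the 4 arrays, which gave 19722 genes, 10626 of them with several probe sets. Probe sets of a gene can disagree, and the text says where they did for the genes chosen by size.

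High salt was compared with normal salt in limma 3.58.1 (R 4.3.3), with lmFit and eBayes on the 4 arrays, no trend, no robust option and no block. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and for each list also over the list alone. Intervals are 95% confidence intervals from the moderated fit, whose prior degrees of freedom were 1.98 beside 2 residual degrees of freedom. The median SD between arrays of a group was 0.188 and the median SE of a difference 0.184. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 33 lists with at least 5 measured members. Camera with an estimated correlation, fry (directional and mixed) and camera on ranks were alternatives. With an estimated correlation, camera's test has only the 2 residual degrees of freedom, so it could hardly pass any of the 33 lists. That correlation is estimated from residuals, which include the gap between the 2 arrays of a medium. Fry's directional p asks whether a list's genes move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes.

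The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists covered regulatory T cell identity and suppressive mediators, Th1, Th2 and Th17 genes, osmotic stress, salt sensing and ion transport, FOXO targets and the naive state, immediate activation, interleukin 2 and STAT5, interferon response, cell cycle, p53, cholesterol synthesis, glycolysis, hypoxia, oxidative phosphorylation, amino acid response, endoplasmic reticulum stress, heat shock, oxidative stress, Wnt, NF-kB, ribosomal proteins, ribosome biogenesis, chemokine and adhesion receptors, apoptosis, and markers of T cells, CD8 and cytotoxic T cells, NK cells, B cells, monocytes and dendritic cells, and platelets and red cells. None was chosen on these samples. The rule named, in each direction, the 12 genes with the largest log2 fold change among those past the threshold, with non-overlapping groups and a mean above the median of all genes. Free places went to genes at an unadjusted p under 0.05 under the same conditions, which here filled all places, and unnamed loci were skipped. It also allowed up to 4 members per list with the smallest p, and always SGK1, NFAT5, FOXP3, IFNG, IL10, IL17A, TBX21, CTLA4, IL2RA, AKR1B1 and SLC5A3. Some results that the rule or the tests gave are not reported here.

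The alternatives were quantile normalization, median centring of each array, the mean of a gene's probe sets, leaving out the dimmest 25% or the dimmer 50% of genes, an intensity trend, robust eBayes, the replicate number as a block, leaving out each array in turn, testing every probe set, an adjusted p under 0.1, a minimum log2 fold change of 1 beside the adjusted p, a linear model with no variance sharing (without 2 genes of zero spread) and the authors' deposited table. Control probe sets were checked per array as values only.

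The gene test was tested on simulated data over 19722 genes with 2 arrays per group. With a spread of 0.1 for every gene, all of the changed genes were recovered, with 9 false calls among the unchanged genes. With the measured spread of each gene, 25.4% of genes changed by 2 on the log2 scale and 65.2% of those changed by 4 were recovered, with 0 false calls. Every array was drawn independently, so a gap shared by same-numbered arrays was not simulated. A shift of 0.25 in the osmotic stress list, with genes simulated independently, was called in 19 of 20 runs. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.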

Results

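Gene expression was measured on 4 arrays of human regulatory T cells, the CD4 T cells that restrain other lymphocytes. The cells had been sorted from healthy controls and were stimulated for 3 days with plate-bound anti-CD3 and soluble anti-CD28, each at 1 µg/mL. The study compared 2 conditions, the usual X-VIVO medium (normal salt, 2 arrays) and the same medium with 40 mM NaCl added (high salt, 2 arrays). The arrays had median log2 expression values of 6.59 and 6.57 in normal salt and 6.57 and 6.53 in high salt. After reduction to the brightest probe set of each gene, 19722 genes were tested. All differences below are the high-salt mean minus the normal-salt mean on the log2 scale. Where leaving out 1 array moved a difference or a list average by over 1.5 times, its lowest and highest value without 1 array follow as a range. The number of arrays limits the precision, and the labels do not say whether arrays of one condition came from separate donors or cultures. The p-values therefore measure only the spread between these samples, which may be technical. With 2 arrays against 2, the smallest two-sided exact permutation p is 0.333, so the tests rest on limma's model of the spread.

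The comparison asked which transcripts and gene programmes of stimulated regulatory T cells differed after exposure to added salt. IFNG, which encodes interferon gamma, the main cytokine of type 1 helper (Th1) T cells, was the gene with the smallest p. Its only probe set gave 6.11 ± 0.03 (SD, n = 2) in normal salt and 7.60 ± 0.11 (SD, n = 2) in high salt. The difference of 1.49 (SE 0.14, 95% confidence interval 1.097 to 1.87) is 2.80-fold, and both high-salt arrays lay above both normal-salt arrays. Among the 20 measured Th1 genes, 17 had a higher mean in high salt, with an average difference of 0.26 over the list. The lymphotoxin gene LTA was higher by 0.96 (SE 0.54, range 0.23 to 1.70) and the chemokine gene CCL4 by 0.89 (SE 0.71, range 0.10 to 1.67), while the chemokine receptor gene CXCR3 was higher by 0.46 (SE 0.29, range 0.13 to 0.79). TBX21, which encodes the Th1 transcription factor T-bet, differed by 0.25 (SE 0.43, range -0.29 to 0.79), within its spread, and by -0.29 without high-salt replicate 2. Adjusted over the list alone, IFNG had a Benjamini-Hochberg adjusted p of 0.00908 in limma and was the only one of the 20 genes to pass 0.05; over all genes its adjusted p was 1. This adjustment was made within each of 33 lists, and IFNG was the 1 gene that passed in any of them. It does not correct for the number of lists, so a single pass may arise by chance. Without variance sharing between genes, the list-alone adjusted p of IFNG was 0.0639, a value added after the data were seen. The Th1 list as a whole had a camera adjusted p of 0.0884. With 1 array left out, the list-alone adjusted p of IFNG was 0.103 without normal-salt replicate 1, 0.0943 without normal-salt replicate 2, 0.0392 without high-salt replicate 1 and 0.107 without high-salt replicate 2, while its difference stayed between 1.40 and 1.57.

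**Figure D1:**
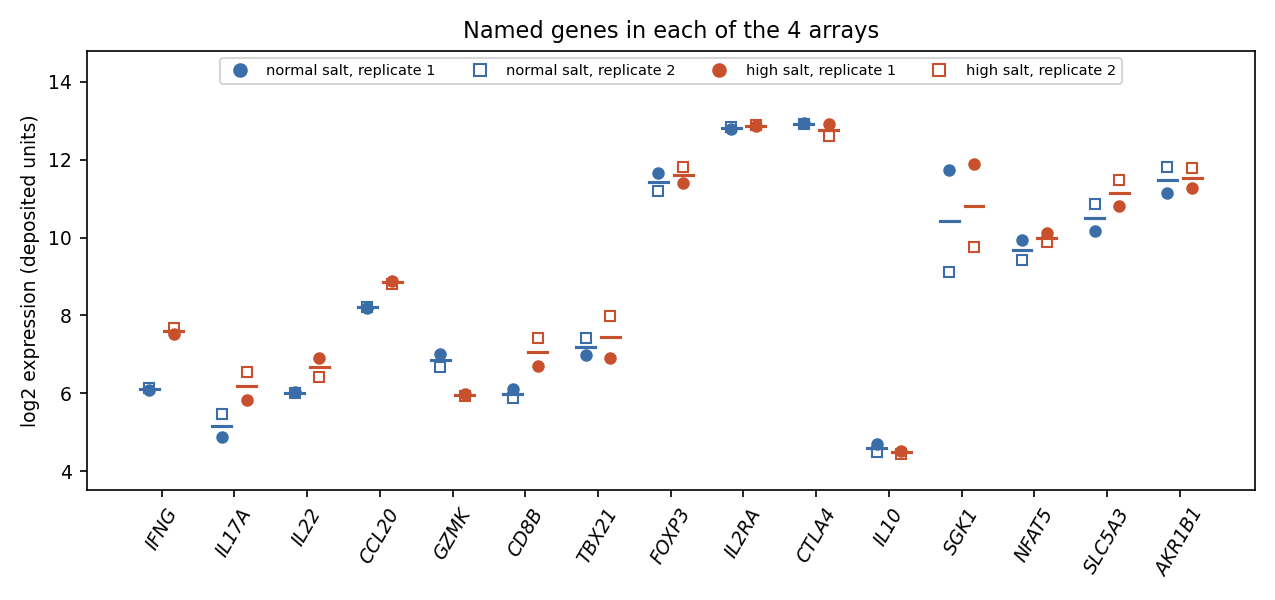
Log2 expression (deposited units, vertical axis) of 15 named genes on each of the 4 arrays, blue for normal salt and red for high salt, filled circles for replicate 1, open squares for replicate 2 and short bars for group means. The 2 high-salt values of IFNG, 7.52 and 7.68, lie above its normal-salt values of 6.09 and 6.14, whereas the arrays of SGK1 separate by replicate number.

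Cytokine genes of type 17 helper (Th17) T cells had higher means in high salt, without passing the test. Of the 20 Th17 genes, 15 were higher and 5 lower, with an average difference of 0.26 (range 0.05 to 0.48) and a camera adjusted p of 0.0596. IL17A was at 5.17 ± 0.42 in normal salt and at 6.19 ± 0.51 in high salt (SD, n = 2 each). The difference was 1.03 (SE 0.35, range 0.67 to 1.38, unadjusted p = 0.0445). Its normal-salt level is near the first quartile of the probe sets (4.96 on both normal-salt arrays), so the size of this difference is uncertain. IL22 was higher by 0.65 (SE 0.21, range 0.40 to 0.89), and CCL20, the ligand of CCR6, by 0.64 (SE 0.13), with both high-salt arrays above both normal-salt arrays for each of the 3 genes. Their adjusted p over all genes was 1, and adjusted over the list alone it was 0.297 for IL17A and IL22 and 0.154 for CCL20. CSF2, which encodes the cytokine GM-CSF, was higher by 0.59 (SE 0.45, range 0.01 to 1.17). With the mean of a gene's probe sets in place of the brightest, the difference of IL17A was 0.54 and that of IL22 was 1.04, and the Th17 list passed the threshold (camera adjusted p = 0.0373). On the brightest probe sets, that list had an adjusted p = 0.93 with an estimated correlation. The estimated correlation of the Th17 list was -0.0127, below the preset 0.01, so correlation between its genes does not account for that higher p. The type 2 helper (Th2) list showed 4 genes higher and 11 lower, with an average difference of -0.06 (range -0.52 to 0.40, camera adjusted p = 0.278).

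The leading markers of regulatory T cells were expressed at high levels in both media, and no gene of the identity list passed the test. FOXP3, their defining transcription factor, was at 11.43 ± 0.34 in normal salt and 11.61 ± 0.29 in high salt (SD, n = 2 each). This difference of 0.18 (SE 0.26, range -0.06 to 0.42) was -0.06 without normal-salt replicate 2 and -0.03 without high-salt replicate 2. IL2RA, the high-affinity interleukin 2 receptor chain, differed by 0.07 (SE 0.13, range 0.04 to 0.09), and CTLA4, an inhibitory receptor, by -0.16 (SE 0.17, range -0.32 to -0.00). Of the 30 regulatory T cell identity genes, 12 were higher and 18 lower (average -0.06, range -0.31 to 0.18, camera adjusted p = 0.286), among them CCR8 at 0.55 (SE 0.32, range 0.14 to 0.96) and GLCCI1 at -0.51 (SE 0.23, range -0.75 to -0.27). Among 20 mediators of suppression, 14 were higher and 6 lower (average 0.02, range -0.08 to 0.12, camera adjusted p = 0.771). The inhibitory cytokine gene IL10 was near the bottom of the scale, at 4.59 ± 0.15 and 4.48 ± 0.05 (SD, n = 2 each), a difference of -0.11 (SE 0.15, range -0.21 to 0.00) that was 0.00 without normal-salt replicate 1. The galectin gene LGALS3 was higher by 0.56 (SE 0.22, range 0.36 to 0.76), or by 0.02 over the mean of its probe sets, and the granzyme gene GZMA differed by -1.003 (SE 0.74, range -1.85 to -0.16). Genes of FOXO targets and the naive state, which keep T cells quiescent and guide them to lymph nodes, were lower in 17 of 21 cases (average -0.14, range -0.62 to 0.34, camera adjusted p = 0.0659), with FOXP1 at -0.18 (SE 0.13), or at -0.07 over the mean of its probe sets. In camera on ranks that list passed (adjusted p = 0.0276), against an adjusted p = 0.93 with an estimated correlation. Chemokine and adhesion receptor genes were higher in 16 of 26 cases (camera adjusted p = 0.836). Their mean of 0.05 (range -0.31 to 0.41) and median of 0.03 were positive and above the median difference of all genes, 0.024. Camera, which compares moderated statistics rather than differences with those of all other genes, placed them lower.

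Osmotic stress genes were more often higher than lower in high salt. Of 22 measured genes of osmolyte transport and the tonicity response, 16 were higher, with an average difference of 0.16 and a camera adjusted p of 0.102. SLC5A3, the sodium-dependent transporter of the osmolyte myo-inositol, was higher by 0.63 (SE 0.37, range 0.29 to 0.98), S100A4 by 0.50 (SE 0.21, range 0.30 to 0.70) and the chaperone gene HSPH1 by 0.31 (SE 0.18, range 0.14 to 0.49). SLC5A3 was at 10.17 and 10.86 in normal salt and at 10.80 and 11.49 in high salt for replicates 1 and 2. Its SE and range thus include the gap between replicates. NFAT5, the transcription factor of the tonicity response, was higher by 0.30 (SE 0.23, range 0.05 to 0.55). AKR1B1, the aldose reductase that makes sorbitol, differed by 0.04 (SE 0.32, range -0.29 to 0.38), with -0.29 without normal-salt replicate 1 and -0.22 without high-salt replicate 2. SGK1, a salt-responsive kinase gene, was at 11.75 and 9.12 in normal salt and at 11.88 and 9.76 in high salt for replicates 1 and 2. Its difference of 0.39 (SE 1.20, range -0.93 to 1.70) was far smaller than the gap between replicates, and it was -0.93 without normal-salt replicate 2 and -0.67 without high-salt replicate 1. In the list of salt sensing and ion transport, 19 of 26 genes were higher (average 0.07, range -0.00 to 0.14, camera adjusted p = 0.729), among them the sodium pump subunits ATP1B1 at 0.41 (SE 0.14) and ATP1B3 at 0.53 (SE 0.20, range 0.31 to 0.74). No gene of either list passed 0.05 adjusted over the list alone, and with the mean of a gene's probe sets the osmotic stress list passed the threshold (camera adjusted p = 0.0346). On the brightest probe sets, that list had an adjusted p = 0.93 with an estimated correlation.

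Interferon-stimulated genes had the highest average of the 33 lists, at 0.36, with 27 of 37 higher and a camera adjusted p of 0.0596. IFIT1 was higher by 1.64 (SE 0.75, range 0.63 to 2.66), HERC5 by 0.85 (SE 0.34, range 0.41 to 1.28), OASL by 0.82 (SE 0.41, range 0.37 to 1.27) and IFI6 by 0.43 (SE 0.20, range 0.21 to 0.64). Camera called the list in opposite directions with 1 array left out: the average was -0.27 without normal-salt replicate 2 (adjusted p = 0.00913) and 1.00 without normal-salt replicate 1 (3.05e-14). With the mean of a gene's probe sets the list passed the threshold in the positive direction (camera adjusted p = 0.0326), and on the brightest probe sets it had an adjusted p = 0.93 with an estimated correlation. Genes of the interleukin 2 and STAT5 response were higher in 12 of 18 cases (average 0.32, range -0.12 to 0.77, camera adjusted p = 0.278), with SOCS1 at 0.80 (SE 0.38, range 0.29 to 1.31), the survival gene BCL2L1 at 0.80 (SE 0.40, range 0.38 to 1.22) and MCL1 at -0.37 (SE 0.19, range -0.57 to -0.17). Immediate T cell activation genes went both ways, 11 higher and 14 lower (average -0.02, range -0.07 to 0.03, camera adjusted p = 0.638), with CD40LG at 0.53 (SE 0.22, range 0.33 to 0.73) and REL at -0.42 (SE 0.15). NF-kB target genes were higher in 13 of 22 cases (average 0.08, range -0.10 to 0.26, camera adjusted p = 0.729).

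**Figure D2:**
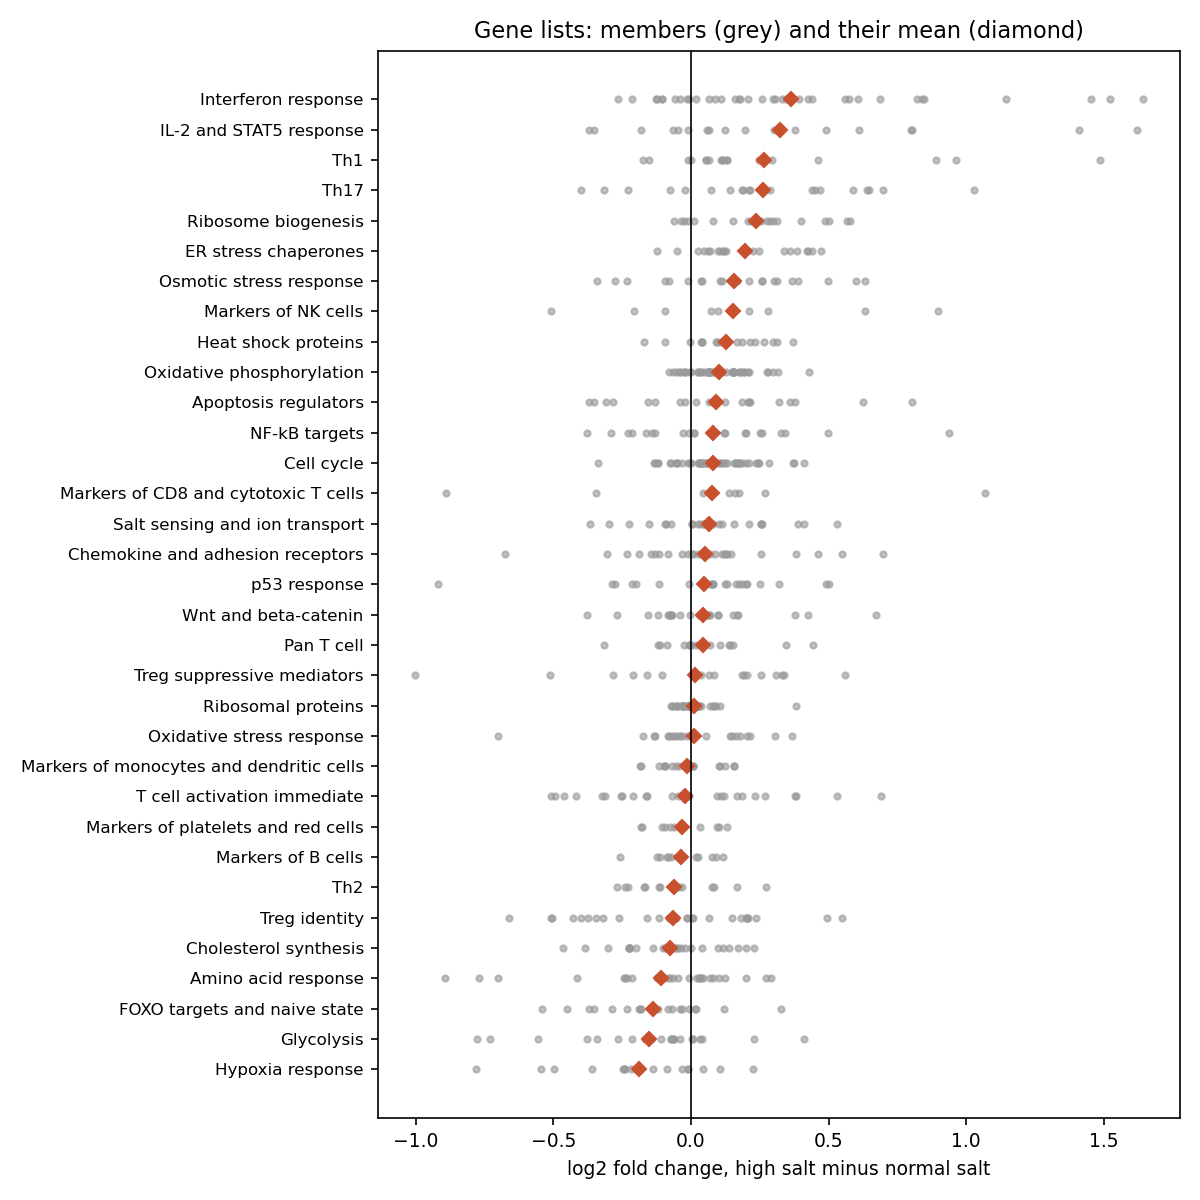
Log2 fold change (high salt minus normal salt, horizontal axis) of the measured members of 33 gene lists, each grey point a gene and each red diamond the list's mean, in order of the mean. The means run from 0.36 for the interferon response to -0.19 for the hypoxia response, and no list passed camera's adjusted threshold.

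The lists of ribosome biogenesis and chaperones had higher averages in high salt, and those of glycolysis and hypoxia lower ones, but none passed the test. Ribosome biogenesis, the assembly of ribosomes in the nucleolus, had the smallest p of the lists, with 17 of 21 genes higher and an average of 0.24 (range 0.05 to 0.42, camera adjusted p = 0.0596, or 0.93 with an estimated correlation). BOP1 was higher by 0.50 (SE 0.32, range 0.19 to 0.81) and MRTO4 by 0.49 (SE 0.33, range 0.06 to 0.92). This list passed the threshold with the mean of a gene's probe sets (camera adjusted p = 0.0129), without the dimmer 50% of genes (0.037) and in camera on ranks (0.0276). Without normal-salt replicate 2, where its average was lowest, camera placed it lower. Chaperones of endoplasmic reticulum stress were higher in 20 of 22 cases (average 0.20, range -0.00 to 0.40, camera adjusted p = 0.0643), with MANF at 0.44 (SE 0.22, range 0.25 to 0.63) and HYOU1 at 0.42 (SE 0.33, range 0.09 to 0.75). Their adjusted p was 0.0276 in camera on ranks, against an adjusted p = 0.93 with an estimated correlation. Heat shock proteins were higher in 15 of 18 cases (average 0.13, range -0.08 to 0.34, camera adjusted p = 0.166). Glycolysis genes were lower in 16 of 22 cases (average -0.15, range -0.67 to 0.36, camera adjusted p = 0.136), including the glucose transporter gene SLC2A3 at -0.56 (SE 0.19, range -0.75 to -0.36). Hypoxia response genes were lower in 15 of 18 cases (average -0.19, range -0.92 to 0.54, camera adjusted p = 0.182), with PDK1 at -0.50 (SE 0.36, range -0.96 to -0.03) and HIF1A at 0.22 (SE 0.14).

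None of the other metabolic and growth lists passed the test. Oxidative phosphorylation genes were higher in 38 of 48 cases, by 0.10 on average (range -0.10 to 0.30, camera adjusted p = 0.166), with NDUFS3 at 0.32 (SE 0.20, range 0.14 to 0.50). Cell cycle genes were higher in 37 of 50 cases, by 0.08 on average (range -0.18 to 0.33, camera adjusted p = 0.286), with CDC6 at 0.41 (SE 0.29, range 0.11 to 0.71) and CDC45 at 0.37 (SE 0.26, range 0.10 to 0.65). Cholesterol synthesis genes were lower in 17 of 24 cases (average -0.08, range -0.38 to 0.23, camera adjusted p = 0.253), and genes of the amino acid response in 17 of 29 (average -0.11, range -0.31 to 0.10, camera adjusted p = 0.394). The p53 response had 15 of 22 genes higher (average 0.05, range -0.06 to 0.15, camera adjusted p = 0.416), including TIGAR at 0.50 (SE 0.17), and apoptosis regulators had 15 of 23 higher (average 0.09, range 0.00 to 0.18, camera adjusted p = 0.608). Wnt and beta-catenin genes were split into 12 higher and 11 lower (average 0.05, range -0.10 to 0.19, camera adjusted p = 0.954, placed lower by camera), with RNF43 at -0.38 (SE 0.13). Oxidative stress genes had a mean of 0.01 (range -0.18 to 0.20) and a median of -0.03 (9 of 21 higher, camera adjusted p = 0.994). Ribosomal protein genes had a mean of 0.01 (range -0.05 to 0.07), a median of -0.00 and 18 of 40 higher (camera adjusted p = 0.664, placed lower by camera).

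Markers of other blood cells were measured because a sort can carry them over. Genes shared by all T cells had an average difference of 0.04 (range -0.07 to 0.16, 9 of 17 higher, camera adjusted p = 0.994), with CD3D at 0.15 (SE 0.14, range 0.08 to 0.23). Among 9 markers of CD8 and cytotoxic T cells, 7 were higher and 2 lower (average 0.08, range -0.06 to 0.22, camera adjusted p = 0.99). Within this list CD8B, a chain of the CD8 co-receptor, was higher by 1.07 (SE 0.29, unadjusted p = 0.0221), and the granzyme gene GZMK was lower, at -0.89 (SE 0.17, unadjusted p = 0.00695). Adjusted over the list alone, their p-values were 0.0995 and 0.0626, so neither passed. CD8A, the other chain of the co-receptor, was at 4.62 and 5.38 in normal salt and at 5.20 and 5.15 in high salt. Its difference was 0.17 (SE 0.30), with no range computed. Both high-salt values lay between the 2 normal-salt values, so the sign depends on the array left out. Among 9 markers of NK cells, 6 were higher (average 0.15, range 0.07 to 0.24, camera adjusted p = 0.488), with NCR3 at 0.90 (SE 0.47, range 0.32 to 1.47) and XCL1 at 0.63 (SE 0.36, range 0.21 to 1.05). Markers of B cells averaged -0.04 (range -0.19 to 0.12, 5 of 12 higher, camera adjusted p = 0.579), those of monocytes and dendritic cells -0.01 (range -0.13 to 0.10, 8 of 19 higher, camera adjusted p = 0.608), and those of platelets and red cells -0.03 (range -0.07 to -0.00, 4 of 10 higher, camera adjusted p = 0.416).

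Over all genes, the largest differences at unadjusted p under 0.05 among genes above the median level are given as values, not as calls. On the higher side were XIRP1 at 1.34 (SE 0.46, range 0.74 to 1.95), KIAA1671 at 1.096 (SE 0.27), SMIM3 at 0.99 (SE 0.25), LINC00515 at 0.89 (SE 0.15), BATF3, a transcription factor gene, at 0.85 (SE 0.30, range 0.51 to 1.19) and C1GALT1C1 at 0.84 (SE 0.18). They were followed by the lysosomal protease gene CTSL at 0.82 (range 0.47 to 1.18), TST at 0.77, CHAC2 and NPTX1 at 0.73, GDF11 at 0.72 and GPR55 at 0.71. On the lower side were LPAR5 at -0.85 (SE 0.27, range -1.16 to -0.53), GPX2, a glutathione peroxidase gene, at -0.80 (SE 0.24), PMS2P5 at -0.71, LINC00115 at -0.65 and ZBTB41 at -0.63. CBLB, a ubiquitin ligase that limits T cell activation, was at -0.62 (SE 0.22, range -0.85 to -0.38), followed by GPATCH2L at -0.58, ZNF767P, EPOR and GAFA3 at -0.57 and SLC2A3 at -0.56. In 3 of these 23 genes (KIAA1671, LPAR5 and EPOR) another probe set had the opposite sign. Over the mean of all probe sets, the differences were 0.29 for KIAA1671, 0.44 for GDF11, 0.47 for GPR55, -0.35 for LPAR5, -0.41 for GPX2, -0.38 for GPATCH2L and -0.25 for EPOR.

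Across all 19722 genes, limma found 0 genes past an adjusted p of 0.05. At an unadjusted p under 0.05 there were 188 genes, 114 higher and 74 lower, which is 0.953% of the genes where chance alone gives 5%. The authors' deposited table likewise listed 0 of 54675 probe sets at an adjusted p under 0.05 and 568 at an unadjusted p under 0.05, with IFNG in first place (p = 0.000499). The groups did not overlap in 4490 genes, or 22.8%, where chance gives 33.3%. Of the 33 lists, camera placed 0 past an adjusted p of 0.05 and 9 at an unadjusted p under 0.05, of which 7 were higher and 2 lower. Camera with an estimated correlation, fry for a shared direction and fry for changes in either direction each gave 0 lists. The first of these has only the 2 residual degrees of freedom and could hardly pass any list. Camera called 4 lists with the mean of a gene's probe sets, 1 without the dimmer 50% of genes and 3 on ranks. Quantile normalization, median centring, leaving out the dimmest 25% of genes and the intensity trend gave 0. The result with the replicate number as a block is given further below. Without normal-salt replicate 1, normal-salt replicate 2, high-salt replicate 1 or high-salt replicate 2, respectively, camera called 10, 12, 8 and 5 lists, and limma gave 601, 117, 490 and 80 genes at an unadjusted p under 0.05, with 0 past the adjusted threshold each time. The average of 26 of the 33 lists changed sign without at least 1 of the arrays, and camera called 7 lists in opposite directions. For interferon response, cell cycle, cholesterol synthesis, glycolysis, hypoxia and oxidative phosphorylation these were without normal-salt replicate 1 and without normal-salt replicate 2. For chemokine and adhesion receptors it called lower without normal-salt replicate 2 and without high-salt replicate 1, and higher without high-salt replicate 2. Leaving out 1 array leaves the other array of that medium alone, so these moves follow from the gap between replicate numbers within that medium. For the interferon response, that gap was -1.27 in normal salt, against a salt difference of 0.36. The moves therefore do not measure how stable the salt difference is apart from the gap. With an estimated correlation and every array kept, the smallest adjusted p of a list was 0.93. In simulations with the measured spread of each gene, 0 of 67 genes changed by 1 on the log2 scale were recovered, 17 of 67 changed by 2, and 43 of 66 changed by 4. The simulated arrays were drawn independently, whereas in the data same-numbered arrays deviated together. Of the unchanged simulated genes, 5.93% reached an unadjusted p under 0.05, so these recovery rates may not carry over to the data.

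Arrays with different replicate numbers differed more than arrays with different salt. The difference between replicates 2 and 1, averaged over both media, reached 1 on the log2 scale in 887 genes, against 40 genes for the salt difference (25 higher, 15 lower). Its average size over the members was larger than that of salt in 30 of the 33 lists. The labels do not say what the number stands for. A measure of RNA quality, the 3' minus the 5' control probe set of ACTB, also went with the number, at 0.78 and 0.82 in replicate 1 and at 0.39 and 0.32 in replicate 2 of normal and high salt.

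**Figure D3:**
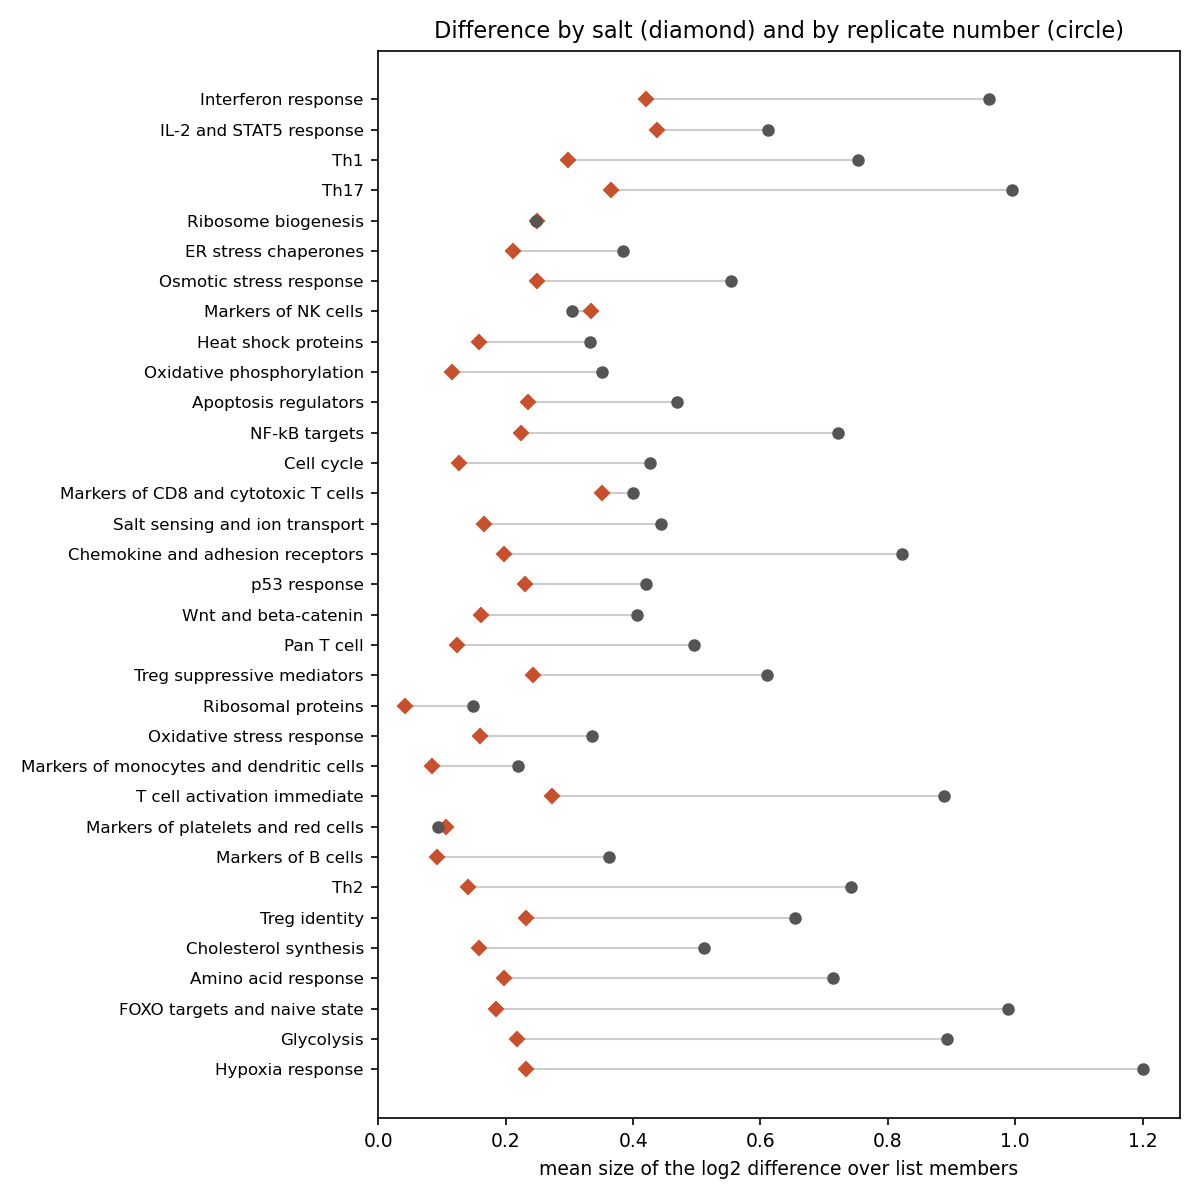
Mean size of the log2 difference over the members of each of 33 gene lists (horizontal axis), red diamonds for high against normal salt and grey circles for replicate 2 against replicate 1. The circle lies to the right of the diamond in 30 lists, and the widest difference by number is 1.20 in the hypoxia response, where the difference by salt is 0.23.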

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

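The count of 0 genes past the threshold was the same under every alternative run: both scalings, the probe set choice, both filters, the variance models, every probe set, the wider threshold, the deposited table and each array left out. The number at an unadjusted p under 0.05 was 188 and moved to 99 without the dimmest 25% of genes, 32 without the dimmer 50%, 566 over every probe set, 533 with no variance sharing and 568 in the authors' deposited table, and ranged from 80 to 601 with 1 array left out. Fewer or more features tested contribute to the counts of the filters and of every probe set. Median centring split the calls into 141 higher and 53 lower (72.7% higher), and leaving out the dimmer 50% into 26 and 6 (81.2%), against 114 and 74 (60.6%). Camera called 4 lists with the mean of a gene's probe sets, 1 without the dimmer 50% of genes, 3 on ranks, and 5 to 12 with 1 array left out, where the lone array is assumed to vary like the other group. These calls are at the preset correlation, and with an estimated correlation and every array kept camera called 0 lists (smallest adjusted p = 0.93). That form of the test has only the 2 residual degrees of freedom. Camera has no robust option, so that alternative was not run for lists. IFNG kept its direction throughout, and its adjusted p over the list alone was 0.00651 to 0.0136 under both scalings, the mean of a gene's probe sets, the 25% filter, the intensity trend and the robust option, and 0.0392 to 0.107 with 1 array left out, where fewer samples remain. For the following alternatives, this list-alone value was added after the data were seen. It was 0.0639 with no variance sharing, where the difference is the same and its error has only 2 degrees of freedom. It was 0.016 over every probe set of the list and 0.00999 from the deposited p-values. The level of IFNG is below the median of all genes, so it has no value without the dimmer 50%. With 1 array left out, the ranges that crossed 0 were -0.21 to 0.0001 for IL10, -0.29 to 0.38 for AKR1B1, -0.93 to 1.70 for SGK1, -0.058 to 0.42 for FOXP3 and -0.29 to 0.79 for TBX21. The sign of CD8A, for which no range was computed, also depended on the array left out. The averages of 26 of the 33 lists crossed 0 too: -0.31 to 0.098 for amino acid response, -0.18 to 0.33 for cell cycle, -0.31 to 0.41 for chemokine and adhesion receptors, -0.38 to 0.23 for cholesterol synthesis, -0.0046 to 0.40 for endoplasmic reticulum stress chaperones, -0.62 to 0.34 for FOXO targets and the naive state, -0.67 to 0.36 for glycolysis, -0.082 to 0.34 for heat shock proteins, -0.92 to 0.54 for hypoxia response. Others were -0.12 to 0.77 for IL-2 and STAT5 response, -0.27 to 1.00 for interferon response, -0.19 to 0.12 for markers of B cells, -0.064 to 0.22 for markers of CD8 and cytotoxic T cells, -0.13 to 0.0998 for markers of monocytes and dendritic cells, -0.10 to 0.26 for NF-kB targets, -0.098 to 0.30 for oxidative phosphorylation, -0.18 to 0.20 for oxidative stress response, -0.056 to 0.15 for p53 response. The rest were -0.067 to 0.16 for genes of all T cells, -0.053 to 0.074 for ribosomal proteins, -0.0039 to 0.14 for salt sensing and ion transport, -0.0714 to 0.0296 for immediate T cell activation, -0.52 to 0.40 for Th2, -0.31 to 0.18 for regulatory T cell identity, -0.084 to 0.12 for suppressive mediators and -0.10 to 0.19 for Wnt and beta-catenin. Of the other alternatives, median centring turned immediate T cell activation (0.0098) and the monocyte and dendritic cell markers (0.0159), the mean of probe sets suppressive mediators (-0.0217) and oxidative stress (-0.0057), quantile normalization oxidative stress (-0.0038), and leaving out the dimmer 50% oxidative stress (-0.008) and ribosomal proteins (-0.0015). With 1 array left out, a move follows from the gap between the 2 arrays of that medium, which carry different replicate numbers. The cause of the other moves was not tested. Values near the bottom of the scale, such as those of IL10, have little signal over background.

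The labels give both media replicates 1 and 2 without saying what the number marks, so it was not treated as a pairing. Deviations from the group means of same-numbered arrays correlated at 0.679 across genes, which are not independent replicates. With the number as a block, 0 genes passed the threshold, 728 were at an unadjusted p under 0.05 (426 higher, 302 lower, 3.69% of the genes), and at the preset correlation camera called 10 lists: higher for Th1 (adjusted p = 0.0133), Th17, osmotic stress, interferon response, endoplasmic reticulum stress, oxidative phosphorylation and ribosome biogenesis (0.0411), and lower for FOXO targets, glycolysis and hypoxia. Without the block, camera at the preset correlation passed 0 lists (adjusted p = 0.0884 for Th1 and 0.0596 for ribosome biogenesis). With an estimated correlation and no block, each of the 10 lists had a camera adjusted p = 0.93. That test has only the 2 residual degrees of freedom and could hardly pass any list, so this value says little about them. Adjusted over the list alone with this block, IFNG (0.00965), IL17A (0.0339) and GZMK (0.0379) passed. GZMK also passed over its list with an intensity trend in the variance model and no block (0.0483).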

Other observations

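Some of the largest differences lay in genes below the median level, outside the rule for named genes, and were chosen after their values were seen. CNKSR3, which encodes a scaffold protein that takes part in sodium channel regulation in the kidney, had the largest log2 fold change of all 19722 genes, at 2.47 (SE 0.57), from 4.56 ± 0.14 in normal salt to 7.04 ± 1.099 in high salt (SD, n = 2 each). Its normal-salt level, like that of IL10, is near the bottom of the scale, where values have little signal over background, so the size of this difference and its rank are uncertain. Over the mean of its probe sets it was 1.30. PRRG4 was higher by 1.85 (SE 0.28), from 5.73 ± 0.22 to 7.57 ± 0.45 (SD, n = 2 each), and had the second smallest p of all genes after IFNG. NOG, which encodes the BMP antagonist noggin, was at -1.19 (SE 0.27). The adjusted p of each was 1 in limma, and both high-salt arrays lay on one side of both normal-salt arrays for each. With 1 array left out, CNKSR3 ranged from 1.70 to 3.25, PRRG4 from 1.53 to 2.17 and NOG from -1.51 to -0.87.

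Arrays with the number 2 differed from those with the number 1 across whole programmes in both media. Hypoxia response genes were higher in replicate 2 by 1.47 on average in normal salt and by 0.75 in high salt, and glycolysis genes by 1.03 and 0.75. Interferon response genes differed by -1.27 and -0.59, and genes of FOXO targets and the naive state by -0.74 and -0.96. Splitting the 4 arrays by number gave 1186 genes past an adjusted p of 0.05 in limma and 4828 at an unadjusted p under 0.05, against 0 and 188 for salt and 0 and 129 for the remaining split. A split that calls many more genes than the real comparison points to a structure of the samples. No explanation of it was tested.

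All tests in the paragraphs that follow were chosen after the results were seen.

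Fewer genes reached an unadjusted p under 0.05 (0.953%) than the 5% chance gives. Noise of dim probe sets is argued against as the whole cause, since the share was 0.325% without the dimmer 50% of genes. A difference shared by same-numbered arrays enters the error of an unblocked comparison. With the replicate number as a block, the share was 3.69%. The median residual SD was 0.112 with the block and 0.188 without it. The block leaves fewer residual degrees of freedom, which by itself lowers the median of such an SD. How much of the drop comes from the shared difference was therefore not settled. The higher share with the block goes with such a difference as part of the cause. Whether it is the whole cause stays open, since the share with the block was still under 5%. What the number stands for is not known, and no biological explanation was tested.

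The higher IFNG value in high salt may have technical or biological sources. The difference was at least 1.51 under quantile normalization and median centring. The arrays were already scaled to each other, with medians from 6.53 to 6.59, so these scalings could hardly lower it. They show that no remaining gap in scale explains the difference, but they do not test the original normalization. More CD8 T cells or NK cells in the high-salt cultures stay open. The 18 measured markers had a median difference of 0.119 (SD over members 0.462), with 13 higher and 5 lower. CD8B was at 1.07, CD8A at 0.17 and GZMK at -0.89. The brightest of them, CST7 and NCR3, were at 11.55 and 9.87 in normal salt, although brightness does not compare amounts between genes. They differed by -0.34 (SE 0.17) and 0.90 (SE 0.47), or by -0.50 to -0.19 and 0.32 to 1.47 with 1 array left out. Of these markers, 4 lay above the median level of all genes and 0 are in another list, and a CD4 sort would remove CD8 T and NK cells. An effect of salt on the regulatory T cells themselves also stays open.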
